A study of Mus musculus with 1000 samples.

How the data were processed

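Whole brains without the cerebellum were collected, mostly at 8 to 12 weeks of age, from descendants of C57BL/6NCrl males given 3 doses of 100 mg/kg ENU, per the labels' protocols. Libraries were made from 4 ng of total RNA with a 3′ cDNA kit and 8 amplification cycles. The 12 samples of a plate row received in-line indices and were pooled before library preparation, and 1152 libraries were sequenced together, per the labels' protocols. The submitters' processing notes name GSNAP, with no version, and the GRCm38 build. How reads were counted or normalised is not given in the sources used here.

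The deposited file was an index of 23231 library names, each assigned by the authors to 1 of 3 data parts. It held no counts, expression values or depths. All 1000 samples were found in it by exact match of the library name, in a single part. The other 22231 names were not used here. The expression tables belong to another series and were not analysed here. Tests of expression between genotypes, between the alleles of Inpp5d and over gene lists had been fixed before the data were examined, and none could be run. The gene lists were those of homeostatic and disease-associated microglia, the interferon response, antigen presentation, astrocytes, reactive astrocytes, oligodendrocytes, neurons, vessels, choroid plexus, cerebellum, blood, and T cells and neutrophils. They have no result here. No gene is named other than the mutated gene in the labels, as the rule for named genes required for a file without expression values.

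Groups were taken from the labels for candidate gene, genotype and subset. Pedigree, plate, well and pool were read from the library names. The association of genotype with pool was tested in each Inpp5d line with a two-sided Fisher-Freeman-Halton exact test by full enumeration, with Benjamini-Hochberg adjustment over the 2 lines and a threshold of 0.05. The enumeration was tested on simulated data, as 200 random tables of 2 rows and 2 columns compared with scipy. The larger tables of all genotypes by pool were not part of that comparison. Alternatives were homozygous against all other libraries, counting the repeated animal name once, and other definitions of the layout counts. Plate column was compared between homozygous and other libraries of each Inpp5d line by exact permutation of genotype within pools, a test added after the layout was seen. Replicate numbers were given in accession order and only name a library. Codon positions were computed from GENCODE M21, which is on GRCm38, the build named in the submitters' notes. They are counted from 1 at the start codon, and coordinates are 1-based. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.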

Results

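The series comprised 1000 libraries of RNA from the brains of mice carrying chemically induced mutations. The mutagen was N-ethyl-N-nitrosourea (ENU), an alkylating agent that introduces point mutations into the germline. Expression was read by 3′ RNA sequencing, which counts fragments near the 3′ end of each transcript, and the stated purpose of the screen was to find mice with abnormal inflammatory states in the brain and the variants behind them. The deposited file used here was an index of library names and held no read count, expression value, sequencing depth or phenotype. The depth of each library is therefore unknown, and expression in the groups described here was not analysed. What could be measured was the layout of the libraries and the position of the labelled mutations in the genome.

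The libraries fell into 8 groups by their labels. The largest, with 920 libraries, was the general screening cohort. A further 48 libraries came from the pedigree ENU43040, for which no genotype was given. The remaining 32 libraries came from lines carrying nonsense alleles of Inpp5d, the gene of the inositol phosphatase SHIP1, which in the brain is expressed mainly in microglia. The W8X line had 6 wild-type (+/+), 7 heterozygous (m/+) and 9 homozygous (m/m) libraries. The S308X line had 3 wild-type, 3 heterozygous and 4 homozygous libraries. Among all 1000 libraries there were 999 distinct animal names. One name was carried by homozygous replicates 3 and 4 of the W8X line, in wells G5 and H2. These may not be separate animals, so the 9 homozygous libraries represent 8 animal names.

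The Inpp5d alleles raise the question of where each premature stop falls. Inpp5d (ENSMUSG00000026288.14) lies on the forward strand of chromosome 1 from 87620312 to 87720507 in GRCm38. The principal protein-coding transcript (ENSMUST00000169754.7) has 27 exons and 1191 coding codons. Codon 8 occupies 87620510 to 87620512 in the coding part of exon 1. Its reference sequence, TGG, encodes tryptophan, and 2 single-base changes turn it into a stop codon. The codon numbered as in S308X occupies 87683749 to 87683751 in exon 9, is TCA in the reference, encodes serine, and also has 2 single-base changes to a stop. The reference residue matched the label of W8X in 3 of 6 protein-coding transcripts with an annotated coding start. It matched the label of S308X in 2 of the 5 such transcripts that are long enough to hold that residue. These matches are by residue number, so a mismatch does not show that a transcript lacks the changed codon. The base changed in the mice was not given in the sources used here, so the sites above rest on these matches. The transcript ENSMUST00000042275.14 matched W8X at the same codon, but its residue numbered as in S308X is glutamate. That residue is encoded by the GAG at 87683752 to 87683754, directly after the TCA. Its numbering at that GAG is thus 1 codon lower than in the principal transcript. The transcript ENSMUST00000163576.1 has glutamine at residue 8 and is too short to hold the other residue. The transcripts ENSMUST00000167032.1 and ENSMUST00000170300.7 start their coding sequence elsewhere and carry leucine at residue 8 and lysine at the residue numbered as in S308X. In both, residue 8 lies at 87681537 to 87681539 and the lysine at 87699689 to 87699691. The TCA matched to S308X lies between these positions, whereas the TGG matched to W8X lies upstream of both. The 2 residues lie in exons 2 and 10 of both transcripts, and these positions lie in exons 7 and 15 of the principal transcript. By its exon bounds, the principal transcript has as many coding codons between these positions as they have. Their coding sequence therefore most likely includes the TCA, under a lower residue number. Their sequence at the TCA itself was not read.

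The comparison of Inpp5d genotypes depends on whether genotype was spread evenly over library pools, because the 12 libraries of a plate row were combined before the sequencing library was made. In the W8X line, pool 39 held 2 wild-type, 4 heterozygous and 4 homozygous libraries, and pool 40 held 4, 3 and 5. Genotype and pool were not detectably associated (Fisher-Freeman-Halton exact test, two-sided p = 0.864, adjusted p = 0.864 over 2 tests). In the S308X line all 4 homozygous libraries were in pool 38, whereas the wild-type and heterozygous groups each had 2 libraries in pool 38 and 1 in pool 39. The exact test gave a two-sided p of 0.467 (adjusted p = 0.864). With the 10 libraries split 8 and 2 over these pools, it cannot give a p below 0.133, so an uneven distribution could not have been detected. The lines overlapped in pool 39 alone, which held 10 libraries of the W8X line and 2 of the S308X line. The remaining 8 libraries of the S308X line were in pool 38 and the remaining 12 of the W8X line in pool 40, so that line and pool were largely confounded.

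**Figure D1:**
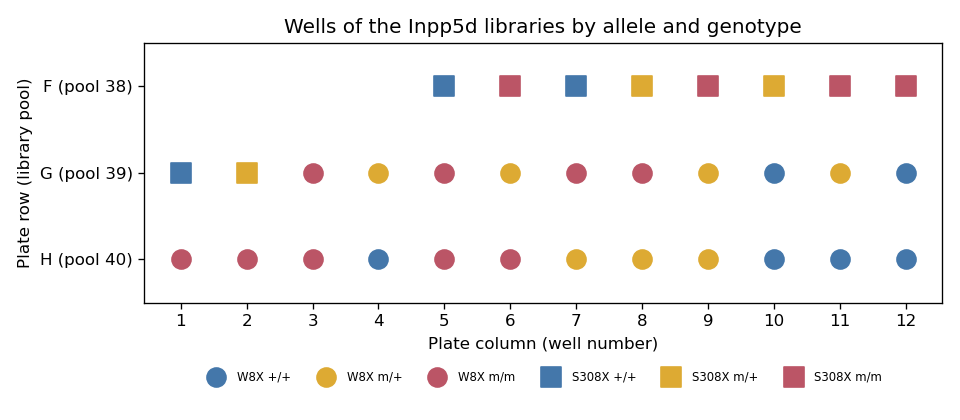
Wells of the 32 Inpp5d libraries, with plate column on the horizontal axis and plate row, equal to library pool, on the vertical axis. Each point is 1 library, circles are the W8X line, squares are the S308X line, and colour gives genotype. All 4 homozygous libraries of the S308X line sit in pool 38.

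In the screening cohort, the library names gave the pedigree of each animal. The median pedigree had 12 libraries, and 66 pedigrees had exactly 12. Another 10 pedigrees had 6 libraries and 41 had fewer than 6. These are counts of libraries in this series and need not be the sizes of the families. Of the 41 pedigrees with fewer than 6 libraries, 40 were on the plate that also held the Inpp5d lines. That plate carried no other screening pedigrees. Its library names carry the tag rep after the plate number, and the names do not say what it means. Each of the 66 pedigrees with 12 libraries occupied 1 pool and was alone in it. In a comparison between these pedigrees, pedigree and pool cannot be told apart. A comparison among siblings of such a pedigree would lie within 1 pool and is not affected in this way. Among the 95 screening pedigrees with at least 2 libraries, 92 lay in a single pool, and no screening pedigree was spread over more than 1 plate. The 48 libraries of ENU43040 filled 4 pools of 1 plate and shared none of them with another pedigree.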

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

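In the W8X line, no alternative run brought the association of genotype with pool past the threshold: the exact p was 1 for homozygous against all other libraries, and 0.750 or 0.742 with the repeated animal name counted once, in pool 39 or pool 40. In the S308X line it was 0.467 for homozygous against all others. The 10 libraries of that line were split 8 and 2 over pools 38 and 39. With that split, neither this test nor the one over 3 genotypes can give a p below 0.133, so these values say nothing about stability. The median number of libraries per pedigree was 12 with all samples included, and 76 screening pedigrees had 6 or more libraries against 66 with 12 or more. None of the screening pedigrees was on more than 1 plate, while 3 were in more than 1 library pool. Alternatives for expression (normalisation, low-count filter, pool as a covariate, each replicate left out) were not run, because the index holds no expression values. No paired analysis was possible because the index holds no measurements and the replicate numbers were given in accession order. Sequencing depth is unknown.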

Other observations

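The following tests were chosen only after the layout had been seen. Plate column is of interest because each sample in a row receives its own in-line index. In the W8X line, the 9 homozygous libraries had a mean plate column of 4.44 and the other 13 libraries one of 8.69. Among these others, the wild-type libraries lay on average in higher columns than the heterozygous ones, a difference that was not tested. The low columns of the homozygous libraries were noticed in pool 40. There the homozygous and other libraries had means of 3.4 and 8.71 (exact permutation test, two-sided p = 0.0101). Pool 39, the part of this line not used to choose the test, had means of 5.75 and 8.67 (exact permutation test, two-sided p = 0.171). The direction was that of pool 40, but placement of genotypes without regard to plate column stays open there with 4 libraries against 6. In pool 39 the animal numbers of this line rose with plate column, so its wells followed animal number. In pool 40 the animal numbers did not rise steadily with plate column. There the homozygous libraries came first, then the heterozygous and then the wild-type ones, except for a wild-type library among the homozygous ones. The permutation treats the libraries of a pool as exchangeable and does not account for an order by animal number. In the S308X line, also not used to choose the test, the 4 homozygous libraries of pool 38 lay in higher columns than the other 4, with means of 9.5 and 7.5 (exact permutation test, two-sided p = 0.343). Permuting genotype within both pools of the W8X line gave an exact two-sided p of 0.00279, which includes the pool that prompted the test. Counting the repeated animal name once, which leaves 8 homozygous libraries, gave 0.00498 with its library in pool 39 kept and 0.00434 with that in pool 40 kept. Whether plate column was linked to genotype by more than chance is left open.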
